A study of Mus musculus with 2 samples.

How the data were processed

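Sorted mesenchymal cells from mouse large intestine were profiled by droplet single-cell RNA sequencing with the 10x Genomics 3' v3.1 chemistry, 1 library per group. Per the labels, the cells were negative for CD45 (leukocytes), EpCAM (epithelium) and CD31 (endothelium) and positive for gp38 (podoplanin, a surface protein of fibroblasts). The library named ff came from C57BL/6 mice and the library named GF from Balb/c mice, and the series' design text names germ-free mice. The sources used here do not spell out the abbreviation ff. The germ-free status of each library is given only by the name GF, so strain and library coincide and status cannot be separated from them.

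Per the submitters' processing notes, the reads were processed with Cell Ranger 6.0.0 on the mm10 mouse genome, and the annotation release is not given in the sources used here. The deposited tables hold raw UMI counts (unique molecular identifiers, 1 per captured transcript) per Ensembl gene and cell barcode, with no normalization by the authors. Both tables list the same 32285 genes. The lowest barcode total was 500 UMIs in each table, so barcodes below that depth had been left out before deposit. Gene symbols were matched by Ensembl identifier for 32158 of the 32285 genes, and coordinates were read from the GENCODE vM21 annotation of GRCm38, the same assembly as mm10.

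The ff library had 13704 barcodes with 119866589 UMIs (median 8685 per barcode) and the GF library 16388 barcodes with 105331294 UMIs (median 6147.5). Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrially encoded genes, which left 12702 ff and 15066 GF cells. Doublets were then removed with Scrublet as implemented in scanpy 1.11.5, at its automatic threshold. It marked 610 ff cells (4.80%) and 847 GF cells (5.62%), and 12092 ff and 14219 GF cells were retained.

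Cells of both libraries were clustered together. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen by their combined rank within each library, and each gene was scaled within its library. After 30 principal components and a graph of 15 nearest neighbours, clusters were found with the Leiden method (leidenalg 0.10.2, resolution 1). Cxcl12 and the members of every gene list that are not cell type markers were left out of the variable genes. Clusters were named from fixed marker lists. A marker counted where its level was at least 2-fold that in all other cells, a name needed at least 3 markers with 1 among the top 20 genes by fold, and a cluster with more markers of another type among its top 10 genes stayed unnamed. The marker lists were set before the data were examined, as were the named-gene rule, the gene lists and the alternatives not described as chosen later. The thresholds for naming were set after seeing the data. Unnamed clusters with fibrillar collagen RNA (Col1a1, Col1a2 and Col3a1) at 25% or more of the median of the named fibroblast-like clusters were kept in the fibroblast-like pool.

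Class levels are UMIs summed over cells and expressed as counts per 1000000 UMIs (CPM). Log2 ratios of Cxcl12 were taken without a pseudocount, and those of other genes after adding 1 CPM, which understates the ratio of genes at low levels. Intervals are exact at the 95% level: Poisson for a CPM, conditional binomial for a ratio (without pseudocount) and Clopper-Pearson for a share. They cover counting error only. With 1 library per group, cells are not replicates and no test between groups was made, so the differences have no replicate check. Genes with at least 50 UMIs over both libraries were measured for GF against ff. For class against class, a gene needed at least 50 UMIs in each library. For each list of at least 5 measured genes, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart when its median lay in the outermost 5% of these, and in the same direction in both libraries for class against class. This describes these libraries and is not a test between groups.

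The genes named for GF against ff were the 12 with the highest and the 12 with the lowest log2 ratio among those with at least 200 UMIs in the pool and the same sign in each of the Foxl1-high-like, lamina propria-like, adventitial or submucosal-like and unnamed fibroblast-like classes. Mitochondrially encoded, ribosomal protein, immunoglobulin, haemoglobin and sex genes and unnamed gene models were left out of this ranking; 4 gene models with higher and 3 with lower ratios passed the last named gene. From each list described, up to 4 members with the largest absolute log2 ratio and at least 200 UMIs were named, by the mean ratio over both libraries, with the same sign in each, for class against class. Some genes that these rules name are not used here. The partner copies of named genes, further clock genes, and Wnt4 and Wnt6 for class against class, were added after their values were seen. Cxcl12, Foxl1 and the sex genes were named in any case. To compare shares of cells with a UMI, each cell was thinned to 2000 UMIs, and shallower cells were left out.

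The ratio and list calculations were tested on simulated counts drawn from the summed barcodes of GF against ff over 15638 genes. Intervals covered the simulated log2 ratio for 94% of genes at -1 and at -0.585, for 98% at 0.585, for 96% at 1 and for 95.75% of unchanged genes. Of the simulated lists without an effect 6.5% stood apart, and of those with 10 of 20 members raised all did. Simulated genes were drawn independently and list members at random, so these shares do not carry over to lists whose genes vary together. Alternatives covered the cell filter, doublets, clustering, scaling, summing over cells, the UMI minimum, the pseudocount and the class mixture. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.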

Results

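The series examined mesenchymal cells of the mouse large intestine, and its title names the chemokine CXCL12 made by Foxl1-high mesenchymal cells. Cells that surround the crypts at the base of the epithelium and express the transcription factor Foxl1 are known as telocytes or subepithelial myofibroblasts. There was 1 library from C57BL/6 mice (ff) and 1 from Balb/c mice (GF), so no difference between them could be set against a spread between replicates. The retained ff cells held a median of 8856.5 UMIs and the retained GF cells a median of 6341. Xist, the RNA of the inactive X chromosome, stood at 782 CPM in the ff library and 1056 CPM in the GF library. The Y-linked genes Ddx3y and Eif2s3y had no UMI in either library, where a floor of 3 counts allows up to 0.0276 CPM in ff and 0.0320 CPM in GF. Uty had 1 UMI and Kdm5d 3 UMIs in each library.

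Fibroblast-like cells made up most of both libraries, at 96.2% of ff cells and 87.4% of GF cells. Of 26 clusters, 2 were Foxl1-high-like, 1 was lamina propria fibroblast-like and 3 were adventitial or submucosal fibroblast-like, the cells known as trophocytes where they express Grem1 and Cd81. A further 9 collagen-rich clusters were not named by the marker rule, though some held markers of a type, and were kept as unnamed fibroblast-like cells; their leading genes included Sfrp2, Col6a5, Stmn2, Ntrk3, Cxcl9, Myoc and Ptn. They made up 49.3% of ff and 51.3% of GF cells. Unnamed clusters closest to the reticular cell markers held 30.1% of ff and 26.5% of GF cells, those closest to the adventitial markers 8.45% and 11.8%, those closest to the lamina propria markers 8.03% and 9.11%, and 1 cluster closest to the pericyte markers 2.71% and 3.90%. None was closest to the Foxl1-high markers. Closest was judged first by reaching 3 markers and then by the share of a list, which favours short lists. The clusters closest to the reticular markers held only 1, 1 and 2 of the 7. Smooth muscle-like cells made up 1.60% of ff and 2.70% of GF cells. Despite the sort against CD45, B or plasma cell-like clusters held 0.554% of ff and 4.54% of GF cells, and T or innate lymphoid cell-like clusters 0.331% and 4.09%.

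The Foxl1-high-like share was lower in the GF library. The class held 2096 of 12092 ff cells, or 17.3% (95% exact interval 16.7% to 18.0%), and 1022 of 14219 GF cells, or 7.19% (6.77% to 7.62%). The lamina propria-like class held 10.3% of ff and 10.1% of GF cells, and the adventitial or submucosal-like class 19.4% and 18.8%. Inside the last, single clusters differed by similar or larger factors and in opposite directions, with the Angptl1-led one at 12.02% and 5.09% and the Efhd1-led one at 0.538% and 6.74%. The unnamed Stmn2-led cluster held 11.2% of ff and 3.09% of GF cells, a larger factor than for the Foxl1-high-like class. Its leading genes Stmn2 and Cck differ between the libraries, and so does Fgfbp1, which with Wif1 leads the larger Foxl1-high-like cluster. Inside the Foxl1-high-like class Wif1 differed little, at 151 CPM in ff and 136 CPM in GF. Within the fibroblast-like pool, which leaves out the lymphocytes, the Foxl1-high-like share was 18.0% in ff and 8.23% in GF. The sort on gp38 sets these shares as well as the tissue does, and GF cells had fewer UMIs. Of the 14 Foxl1-high markers, 5 differed at least 1.5-fold between the libraries inside the class; clustering without any gene that differed that much, an alternative chosen after seeing the data, gave 17.3% and 7.18%. One cluster, led by Wif1, held most of the class in both libraries (1514 ff and 854 GF cells), and a smaller one led by Nrg1 held 582 and 168. Foxl1 itself, which helped to define the class, stood at 55.1 CPM (51.9 to 58.6) in its ff cells and 90.8 CPM (84.1 to 97.7) in its GF cells. The clusters differed in opposite directions: the Wif1-led one had 45.3 CPM in ff and 97.5 CPM in GF, and the Nrg1-led one 76.0 CPM (69.3 to 83.2) and 55.4 CPM (43.0 to 70.2). After thinning, a Foxl1 UMI was seen in 8.67% of Foxl1-high-like cells in ff and 16.5% in GF (32.7% and 43.6% unthinned), and in 0.665% and 1.04% of the other fibroblast-like cells (3.28% and 3.24% unthinned). Among lymphocytes, which should lack Foxl1, the thinned share was 0.935% of 107 ff cells (exact interval 0.0237% to 5.10%, median 4480 UMIs), and none of 1023 thinned GF cells (median 2582 UMIs) held a UMI. Smooth muscle-like cells also held Foxl1, at 52.1 CPM in ff and 63.6 CPM in GF.

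**Figure D1:**
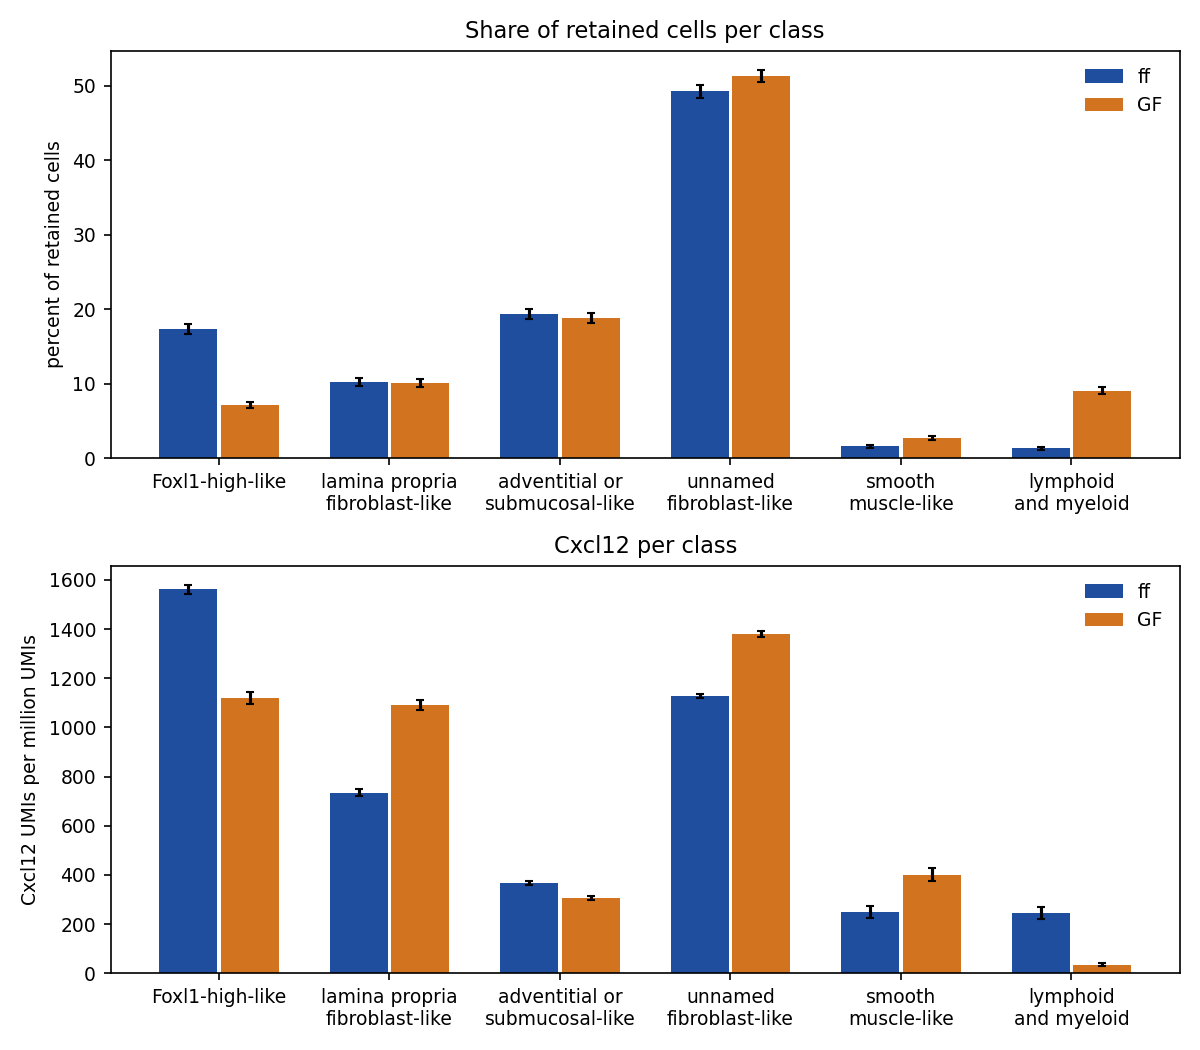
Upper panel, share of retained cells per class in percent, and lower panel, Cxcl12 UMIs per 1000000 UMIs per class, for the ff library (blue) and the GF library (orange), with 95% exact intervals of counting error as bars. The Foxl1-high-like share was 17.3% in ff and 7.19% in GF, and its Cxcl12 level 1562 and 1120 CPM.

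Cxcl12 UMIs were present in each fibroblast-like class, and the Foxl1-high-like class had the highest level of the fibroblast-like classes in the ff library. Cxcl12 (ENSMUSG00000061353, protein-coding, chromosome 6, 117168535 to 117181367, plus strand, GRCm38) encodes the ligand of the receptor CXCR4. Foxl1 (ENSMUSG00000097084) lies on chromosome 8 from 121127940 to 121130644. In ff, Cxcl12 reached 1562 CPM (1544 to 1579) in Foxl1-high-like cells, 1128 CPM in unnamed fibroblast-like, 734 CPM in lamina propria-like and 366 CPM in adventitial or submucosal-like cells. The log2 ratio of Foxl1-high-like over all other fibroblast-like cells was 0.80 (0.78 to 0.82). In GF, the class stood at 1120 CPM (1096 to 1144), close to the lamina propria-like cells at 1091 CPM and below the unnamed cells at 1380 CPM, and the adventitial or submucosal-like cells had 307 CPM. The ratio there was 0.07 (0.04 to 0.10), and it was -0.12 with median-of-ratios scaling and -0.03 after thinning, so no direction was read from it. Against the named lamina propria-like and adventitial or submucosal-like classes alone, an alternative chosen after seeing the data, the log2 ratio was 1.58 in ff and 0.92 in GF. Within the class the Wif1-led cluster had 1907 CPM in ff and 1226 CPM in GF, and the Nrg1-led cluster 834 and 560 CPM. The unnamed cluster led by Col6a5, which that comparison leaves out, had 2145 and 2046 CPM, above both. It is closest to the lamina propria markers, with 4 of the 9. It stayed unnamed because more haemoglobin genes than lamina propria markers were among its top 10 genes. Haemoglobin RNA made up 0.0725% of its UMIs. The ratios of 1.58 and 0.92 therefore rest on that naming rule.

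After thinning to 2000 UMIs, 86.7% of Foxl1-high-like and 69.3% of other fibroblast-like ff cells held a Cxcl12 UMI (97.9% and 90.5% unthinned), and 77.6% and 70.9% in GF (96.6% and 87.0% unthinned). Thinning left out 9 Foxl1-high-like and 220 other cells in ff, and 4 and 385 in GF. Lymphocytes, which served as a measure of free RNA, held a Cxcl12 UMI in 15.9% of ff and 4.30% of GF cells after thinning, with unthinned medians of 4480 and 2582 UMIs. By level, the largest ff lymphocyte cluster, of 44 B cell-like cells, had 22.9 CPM (6.25 to 58.7), below the lowest fibroblast-like cluster with at least 50 cells (Efhd1-led, 115 CPM, 91.7 to 143). The 3 B or plasma cell-like clusters of ff ranged up to 1120 CPM, in 3 cells, and the 40 T or innate lymphoid-like cells of ff had 441 CPM (362 to 532), with a UMI in 27.5% of them. That is above the 366 CPM of the adventitial or submucosal-like cells of ff. By level, then, not each fibroblast-like class of ff exceeded the lymphocytes. In GF the B or plasma and T or innate lymphoid-like cells had 28.4 and 29.9 CPM. By share, both classes of fibroblast-like cells lay above that background, and no order between the classes was read from the GF shares, because the thinned level went the other way. Blood endothelium-like cells, few in number after the sort, had 1682 CPM in ff (40 cells) and 642 CPM in GF (28 cells).

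Foxl1-high-like cells differed from the other fibroblast-like cells in the signals they carried for the epithelium. List medians were higher for BMP ligands, which favour epithelial differentiation. They were lower for WNT ligands and R-spondins, which sustain stem cells, and for chemokines, with members on both sides in each list. Cell type markers were left out of these medians, among them the Foxl1-high markers Wnt5a, Bmp5 and Bmp7 and the adventitial marker Rspo3. The medians therefore do not cover all WNT and BMP signals of the class. Of the 28 lists measured without cell type markers, 14 stood apart in the same direction in both libraries. Ratios are given as log2 of Foxl1-high-like over other fibroblast-like cells, ff first and GF second; the median over all genes was 0.10 in ff and 0.17 in GF, and median-of-ratios scaling shifts each ratio down by 0.11 and 0.19. The BMP ligands had medians of 1.40 and 1.07 over 8 genes (5 and 6 at least 1.5-fold higher, 2 and 2 that much lower). Bmp3 stood at 4.60 and 3.81, Bmp2 at 2.45 and 3.38 (875 against 160 CPM in ff, 1254 against 119 CPM in GF) and Inhba, an activin subunit, at 1.94 and 2.02, whereas Gdf10 stood at -3.69 and -4.68 (2 UMIs in the GF class; interval without pseudocount -9.96 to -5.06). The WNT ligands and R-spondins had medians of -1.36 and -0.78 over 10 genes (7 and 6 that much lower, 1 and 1 higher), with Wnt2 at -4.16 and -4.23, Rspo1 at -2.60 and -2.84 (1 UMI in the GF class; interval without pseudocount -11.07 to -3.28), Wnt2b at -1.64 and -3.17 and Wnt9a at -1.62 and -2.19. Wnt4, the most abundant of them (214 against 215 CPM in ff, 227 against 228 CPM in GF), hardly differed, and Wnt6 was higher by 0.80 and 0.73. Secreted WNT inhibitors went both ways. Wif1 was higher by 6.50 and 6.57, while Sfrp2 stood at -5.57 and -5.10, Sfrp4 at -4.65 and -5.27 and Sfrp1 at -4.16 and -4.66, which left the list median at -4.16 and -3.82 over 7 genes. BMP antagonists had medians of -0.86 and -0.97 over 9 genes. Chrdl1 stood at -3.41 and -3.67, but Nbl1 was higher by 2.39 and 2.48 and Fst, which binds activin, by 1.68 and 3.65. With a minimum of 500 UMIs the median of this list turned to 0.16 and 0.55.

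The chemokine list had medians of -0.52 and -0.93 over 16 genes (7 and 9 at least 1.5-fold lower, 2 and 2 that much higher). Cxcl12 is 1 of the 16 and, in ff, 1 of the 2 that were that much higher. The monocyte attractants Ccl2 (-3.54 and -3.79) and Ccl7 (-3.14 and -3.38) and the CXCL12 scavenger receptor Ackr3 (-2.35 and -2.29) were lower in Foxl1-high-like cells, and Cxcl14 was higher (3.37 and 2.38). Growth factors stood apart in ff alone, with medians of -0.42 and 0.00 over 28 genes. The EGF-family ligand Nrg1 (3.05 and 4.29) and Fgf9 (3.33 and 4.55) were higher, and the neurite growth factor Ptn (-3.76 and -4.07) and the lymphatic growth factor Vegfd (-1.87 and -2.80) were lower. In prostaglandin metabolism, with medians of 0.35 and 0.33 and standing apart in ff alone, the efflux pump Abcc4 (3.04 and 2.03), the cyclooxygenase Ptgs1 (1.98 and 1.81) and the receptor Ptger2 (1.18 and 1.65) were higher. The receptor Ptger3 had no UMI in the GF class. Retinoid genes, standing apart in GF alone, split by member. Aldh1a1 (3.07 and 3.18) and the retinol carrier Rbp4 (2.62 and 2.70) were higher, Aldh1a3 (-4.22 and -4.30) was lower, and the medians were -0.12 and -0.66.

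Outside the niche signals, contractile genes and cholesterol synthesis were higher in Foxl1-high-like cells of both libraries. The 6 contractile genes that are not markers had medians of 1.80 and 2.29, with Mylk at 4.19 and 3.56 and Myl9 at 3.65 and 3.72. Of 22 cholesterol genes, 19 in ff and 18 in GF were at least 1.5-fold higher and none was that much lower. Their medians were 0.98 and 1.08, with Sqle at 1.81 and 2.23. Interferon-stimulated genes had medians of 0.45 and 0.48 over 36 genes, with Ifit3 at 1.68 and 1.99, and glycolysis had 0.41 and 0.44 over 16 genes, with Pkm at 1.002 and 0.92. Complement genes had medians of -1.14 and -1.002 over 10 genes, with 6 at least 1.5-fold lower, 1 that much higher and 3 between in each library, and with C4b at -4.99 and -4.24. Microbial sensing and NF-kB genes had medians of -0.61 and -0.55 over 32 genes. The alarmin Il33 (-5.04 and -5.38) and Il6 (-3.61 and -4.18) were lower, but Il1rl1, which encodes the receptor of IL-33, was higher (3.23 and 4.17). Matrix glycoproteins and proteoglycans had medians of -0.48 and -0.99 over 33 genes, with elastin (Eln) at -4.98 and -4.88. Glucocorticoid response genes and metallothioneins had medians of -0.99 and -1.15, with the glucocorticoid-activating enzyme Hsd11b1 at -4.80 and -4.31 and Mt3 higher at 4.16 and 4.22. Ribosomal protein genes had medians of -0.20 and -0.29 over 80 genes. The remaining lists did not stand apart in both libraries.

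**Figure D2:**
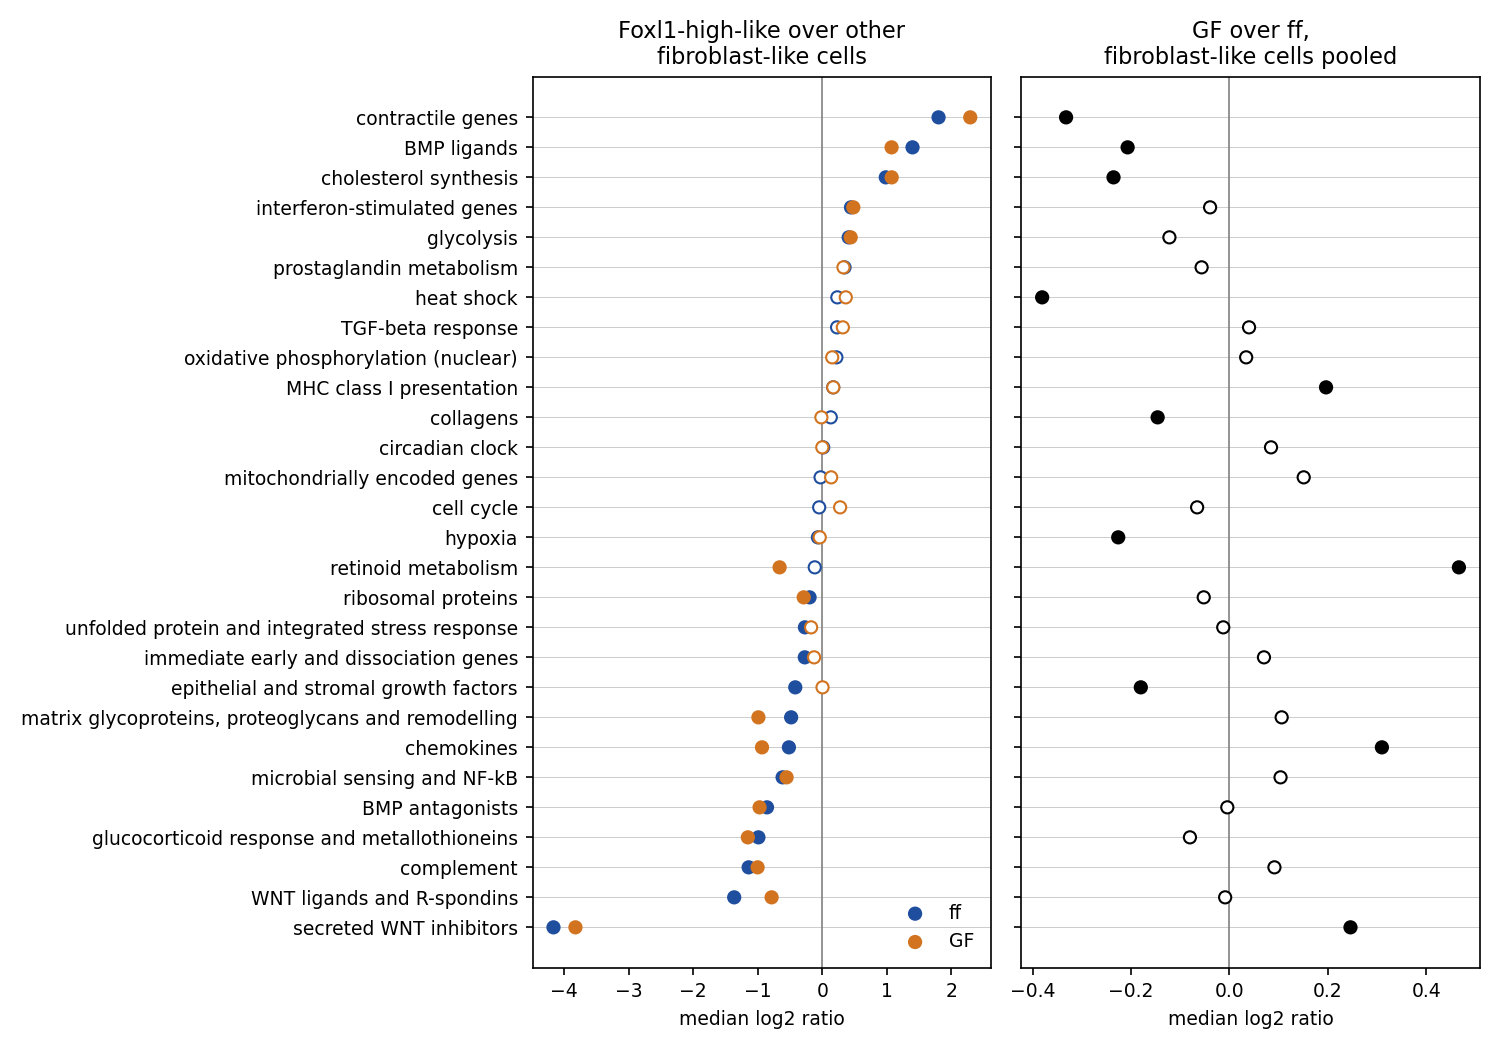
Median log2 ratio per gene list. Left, Foxl1-high-like over other fibroblast-like cells in ff (blue) and GF (orange), without cell type markers; right, GF over ff in the pooled fibroblast-like cells; filled points lie in the outermost 5% of 10000 matched random lists. BMP ligands and cholesterol synthesis lie to the right in both libraries on the left panel, and retinoid metabolism has the highest median on the right panel, at 0.47. Lists without a class comparison, such as MHC class II presentation, are not drawn.

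Between the libraries, Cxcl12 differed by class. It was lower in the Foxl1-high-like cells of GF, with a log2 ratio of GF over ff of -0.48 (-0.51 to -0.45), and higher in the other fibroblast-like cells, with 0.25 (0.24 to 0.26). It was lower in both Foxl1-high-like clusters, by log2 ratios of -0.64 (Wif1-led) and -0.57 (Nrg1-led). In lamina propria-like cells the ratio was 0.57 (0.53 to 0.61). Of 13 fibroblast-like clusters with at least 50 cells in each library, 7 had a higher level in GF and 4 a lower one with counting intervals that leave out 0, and the intervals of the Pi16-led and Efhd1-led clusters held 0. In the whole pool the level was 1020 CPM in ff and 1072 CPM in GF, a ratio of 0.07 (0.06 to 0.08). That value turned to -0.06 with the stricter cell filter and to -0.38 over the named classes alone, so no direction was read for the pool. The adventitial or submucosal-like class had 366 and 307 CPM, but different clusters held most of it: the Angptl1-led cluster held 1453 of its ff cells and 724 of its GF cells, the Pi16-led cluster 825 and 992, and the Efhd1-led cluster 65 and 958. Foxl1 over the pool stood at 13.4 CPM in ff and 13.1 CPM in GF, a log2 ratio of -0.03 that turned to 0.64 with GF clusters weighted by the ff shares.

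Among all 14783 genes measured in the pool, the median log2 ratio of GF over ff was 0.02. The complement protease genes C1rb (0.229 CPM in ff, 120 CPM in GF, log2 ratio 6.62) and C1s2 (0.333 and 109 CPM, 6.36) led, and their close copies C1ra and C1s1 were lower in GF, at 292 and 144 CPM and at 616 and 444 CPM. The 4 genes lie on chromosome 6, with C1ra from 124512405 and C1s2 ending at 124636085. Ifi202b, an interferon-inducible gene, had 0.124 and 71.4 CPM (6.01) and the tropomyosin copy Tpm3-rs7 2.33 and 182 CPM (5.78). Gbp2b, a guanylate-binding protein, had no UMI in ff and 49.2 CPM in GF, which is at least 1723-fold higher against a floor of 3 counts in the ff pool. The fibroblast growth factor-binding protein Fgfbp1 (5.59) was higher in Foxl1-high-like cells by 8.35 (0.931 and 630 CPM) and stood at 0.790 CPM or less in each other class of either library. Lrat, which esterifies retinol, stood at 4.16 with 1.20 and 38.3 CPM, and at 5.89 in lamina propria-like cells. Ralgps2 (3.31), Gimap6 (2.97), BC004004 (2.77), the clock repressor Nr1d1 (2.76) and Cyp4b1 (2.67) followed.

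Genes lower in GF were led by Trim12a, a TRIM-family gene with 26.9 CPM in ff and 0.0924 CPM in GF (log2 ratio -4.67). Stmn2, a microtubule regulator best known from neurons, had 275 and 10.7 CPM (-4.56), and Cck, the hormone cholecystokinin, 15.8 and 0.774 CPM (-3.25). Both are among the leading genes of 1 unnamed cluster. The peptide transporter Slc15a2 and the claudin-family gene Cldn34c1 had no UMI in GF against 11.6 and 6.12 CPM in ff, at least 336-fold and 177-fold lower. The scaffold protein gene Mpp7 (-3.50), Rab6b (-3.12), the basement membrane collagen Col4a6 (-3.05, 38.0 and 3.72 CPM), the protocadherin Pcdh9 (-3.00), Isoc2b (-2.83) and Pnp2 (-2.78) followed. Cck ranged from -3.83 in the unnamed cells to -0.70 in Foxl1-high-like cells. For the 14 of the 24 named genes with at least 50 UMIs in each library, the counting interval of the log2 ratio had a median half-width of 0.17 and a largest of 0.36. All 24 genes, of which 1 is not used here, kept their direction under the 5 alternatives tried. With GF clusters weighted by the ff shares, Cyp4b1 stood at 1.80, Fgfbp1 at 6.53 and Stmn2 at -3.97.

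**Figure D3:**
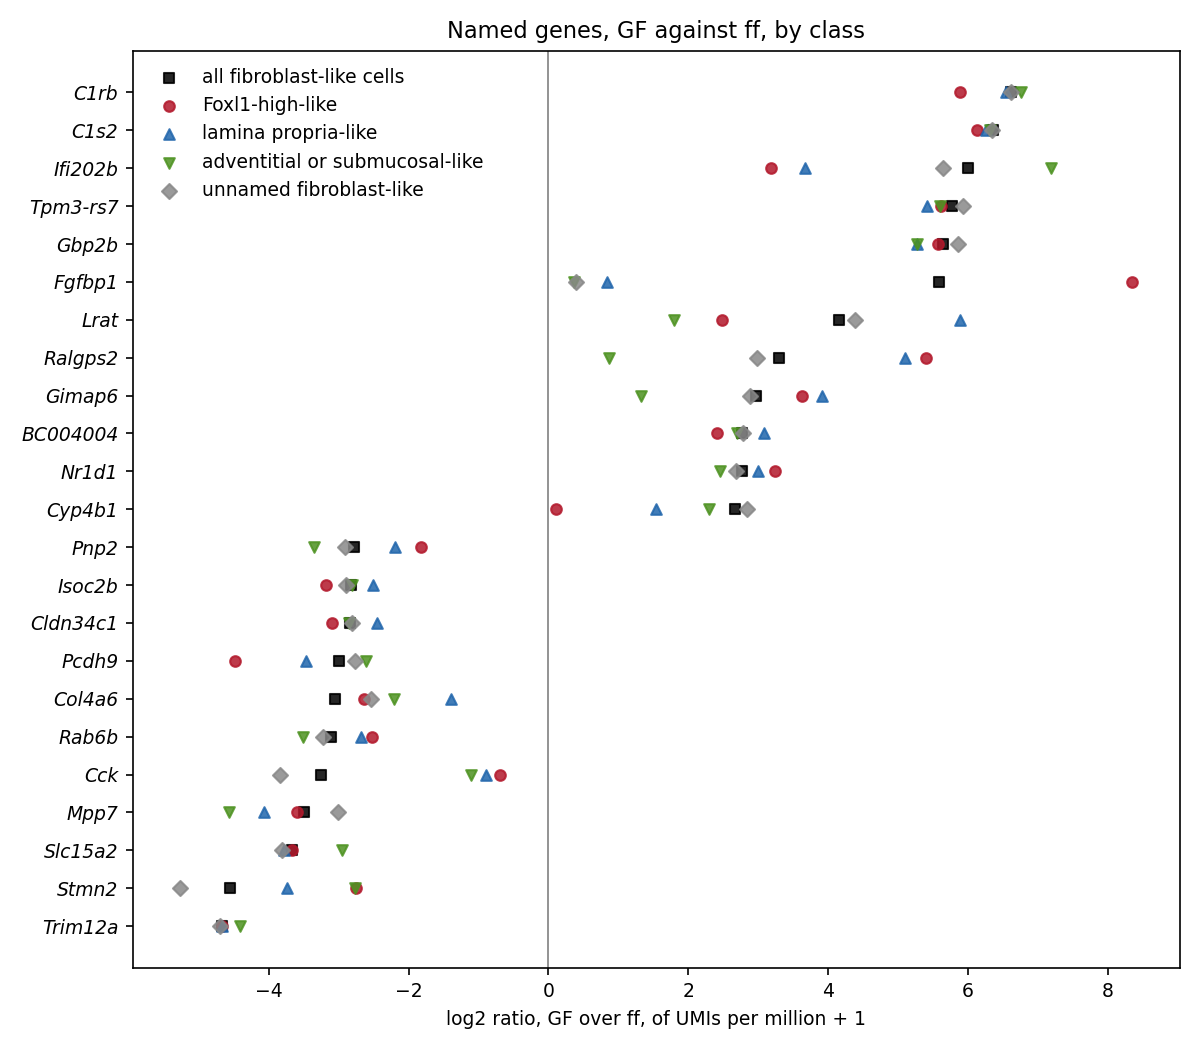
Log2 ratio of GF over ff (CPM plus 1) for the named genes, in all fibroblast-like cells (black squares) and in each class (coloured symbols). C1rb, C1s2, Tpm3-rs7, Gbp2b and Trim12a lie at nearly the same ratio in each class, whereas Fgfbp1 has 8.35 in Foxl1-high-like cells and 0.36 in adventitial or submucosal-like cells, where it lies under 1 CPM in both libraries.

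By gene group, list medians were higher in GF for retinoid metabolism and antigen presentation and lower for heat shock, cholesterol synthesis, hypoxia and growth factors, though in most of these lists most members differed less than 1.5-fold. Of 31 lists measured, 14 stood apart. The retinoid list had a median log2 ratio of 0.47 over 12 genes (5 at least 1.5-fold higher, 1 that much lower), with Lrat, the retinoic acid-degrading enzyme Cyp26b1 (1.16) and the retinoic acid-making enzyme Aldh1a2 (0.72). MHC class II presentation had 0.68 over 6 genes (3 at least 1.5-fold higher, 1 that much lower), with H2-Aa (1.21), Cd74 (1.15) and H2-Ab1 (1.10) higher and H2-DMb1 (-1.83) lower; Cd74 stood at 15.6 CPM in GF, where lymphocytes were also more frequent. MHC class I presentation had 0.20 over 15 genes (3 that much higher), with H2-D1 (1.09, 750 and 1593 CPM), H2-Q6 (0.998) and H2-Q7 (0.65) higher and H2-Q4 (-0.58) lower. MHC class II stood apart in 9 of 10 alternative settings and class I in 7 of 10. Class II did not stand apart with a minimum of 10 UMIs per gene, and its median was 1.01 with GF clusters weighted by the ff shares. These genes vary in sequence between mouse strains. Heat shock genes had -0.38 over 12 genes, 4 of them at least 1.5-fold lower: Hspb1 (-1.26), Hsph1 (-1.17), Hspa1b (-0.99) and Hspa1a (-0.81). Cholesterol synthesis had -0.24 over 22 genes (2 that much lower), with Sc5d (-0.69), Hmgcs1 (-0.69), Cyp51 (-0.52) and Msmo1 (-0.46). Hypoxia genes had -0.23 over 13 genes (1 that much lower), with Egln3 (-0.68), Ankrd37 (-0.52), Adm (-0.49) and Ero1l (-0.48), and growth factors -0.18 over 29 genes (3 that much lower), with Igf2 (-1.39), Nrg1 (-0.86), Edn3 (-0.60) and Hbegf (-0.51). By class, the growth factor median was -0.02 in Foxl1-high-like, -0.20 in lamina propria-like, -0.15 in adventitial or submucosal-like and -0.16 in unnamed cells. Nrg1 was not lower in the Foxl1-high-like cells of GF, at 232 CPM in ff and 268 CPM in GF. In the other fibroblast-like cells it had 27.1 and 12.7 CPM.

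Of the 10 alternative settings, contractile genes stood apart in 9, chemokines in 7, and BMP ligands, secreted WNT inhibitors and collagens in 6. Chemokines had a median of 0.31 over 23 genes, and 0.04 when GF clusters were weighted by the ff shares. Cxcl13, a B cell attractant, stood at 1.70 and the eosinophil attractant Ccl11 at 1.19, while Cxcl2 stood at -1.41, with a negative ratio in each class, and Ccl27a at -1.23. Contractile genes had -0.33 over 14 genes and -0.01 weighted, with Tpm2 (-0.87), Myh11 (-0.84), Acta2 (-0.71) and Tagln (-0.67). BMP ligands had -0.21 and turned to 0.05 weighted, with the Foxl1-high marker Bmp5 (-1.28), Gdf11 (-1.03) and Inhbb (-0.45) lower and Gdf10 (0.91) higher. Secreted WNT inhibitors had 0.25 over 8 genes and 0.08 weighted, with Sfrp4 (0.83) and Frzb (0.58) higher and Wif1 (-1.12) and Dkk3 (-0.49) lower. The value of Wif1 is that of the pool, and inside the Foxl1-high-like class it stood at 151 CPM in ff and 136 CPM in GF. Collagens had -0.15 over 23 genes and -0.08 weighted, with Col4a6, Col12a1 (-0.63) and Col4a5 (-0.53) lower and Col6a5 (1.82) higher. Free RNA of plasma cells and of epithelium stood apart in each of the 9 and 8 settings where enough of its genes were measured. Plasma cell genes had a median of -1.03 over 7 genes, with Igha (-2.23), Jchain (-1.89), Igkc (-1.63) and Iglc1 (-1.03), and genes of epithelium had -0.32 over 11 genes, with Cldn3 at 1.26. The haemoglobin gene Hbb-bs stood at 108 CPM in ff and 71.7 CPM in GF.

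Lists that did not stand apart held members that differed. In the circadian clock list (median 0.08 over 17 genes) Nr1d1, Dbp (1.55), Nr1d2 (1.06) and Per1 (0.997) were higher in GF. These were the 4 at least 1.5-fold higher, and 0 were that much lower. Cry1 (-0.44), Per2 (-0.37), Arntl (-0.27) and Npas2 (-0.21) were lower by less, and Clock (-0.03) and Per3 hardly differed. In complement (0.09) Cfd (2.62, with 2 UMIs in ff; 8.11 without pseudocount, 6.24 to 11.15), Cd59a (1.27) and Cfb (1.21) were higher and C1ra (-1.01) was lower. In microbial sensing and NF-kB (0.10 over 34 genes) Il11 (1.72), Irak3 (0.87) and Nfkbie (0.66) were higher and Tnfaip3 (-1.09) was lower, and in interferon-stimulated genes (-0.04 over 39 genes) Ifit3 (-1.03), Rsad2 (-0.93) and Ifi27l2a (-0.74) were lower and Psmb9 (0.84) was higher. BMP antagonists (0.00) held Fst (1.84) on the higher side and Grem1 (-0.92) on the lower. Prostaglandin metabolism (-0.06) held the degrading enzyme Hpgd (1.27), and WNT ligands and R-spondins (-0.01) held Wnt6 (-0.96) and Wnt2 (0.45). In matrix genes (0.11 over 35 genes) Eln (0.89) was higher and the Foxl1-high marker Tnc (-1.33), Ogn (-1.001) and Postn (-0.85) were lower. The TGF-beta response (0.04) held Tgfbi (-1.63), the unfolded protein response (-0.01) Trib3 (1.78), glucocorticoid response genes and metallothioneins (-0.08) Zbtb16 (1.01), and the cell cycle list (-0.07) Mcm6 (-1.66). Ribosomal proteins (-0.05 over 80 genes) held Rpl29 (-2.72) and Rpl26 (-1.27). Immediate early genes (0.07), nuclear oxidative phosphorylation genes (0.03 over 91 genes), mitochondrially encoded genes (0.15) and glycolysis (-0.12) completed the lists.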

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

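In this part, the tests on UMI depth, on Ptprc and on smooth muscle-like cells were written before their result was seen, and the tests on dilution, differing genes, the number of libraries, collagen RNA, the UMIs of lymphocyte barcodes, gene copies and the cluster mixture were chosen only after it was seen. A first test of gene copies over 5 pairs together, written before, was undecided with 2 of 5 pairs and was then divided. The bound used for the smooth muscle-like cells was set after their value was seen.

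Cxcl12 drew attention because it differed in opposite directions by class, with a log2 ratio of GF over ff of -0.48 in Foxl1-high-like cells and 0.25 in the other fibroblast-like cells. The difference was not tested, since there was 1 library per group. Lymphoid and myeloid clusters drew attention because the sort was meant to remove them, and they held 1.32% of ff and 9.07% of GF cells.

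The Foxl1-high-like share was lower in the GF library. Dilution by cells outside the fibroblast-like pool is argued against by the share of the pool, where the ratio of ff over GF was 2.19. Dilution by other fibroblast-like cells cannot be judged from that ratio, because they are part of the pool. Clustering without differing genes gave a ratio of 2.41. Those genes were chosen among cells already in the class, so cells that had crossed its border could not show. Moved cluster borders therefore stay open. Outside the class, Foxl1 stood at 8.17 CPM in ff and 19.0 CPM in GF in lamina propria-like cells. It stood at 4.13 and 4.58 CPM in unnamed fibroblast-like cells, and at 0.480 and 0 CPM in adventitial or submucosal-like cells. Depth is argued against by pool cells with 5000 to 10000 UMIs, where the class made up 19.3% of 6099 ff and 9.11% of 7451 GF cells, a ratio of 2.12. Strain, germ-free status and the yield of a single library may each be the cause, and with 1 library per group they cannot be told apart; the labels give the status only by the name GF.

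Lymphocytes in the GF library held fibrillar collagen RNA at 1.78% of the level of the fibroblast-like pool, which argues against fibroblast droplets that took up free lymphocyte RNA. Their median of 2582 UMIs was 38.6% of that of the pool, which argues against droplets with a lymphocyte and a fibroblast. After thinning, 76.2% of them held a UMI of Ptprc, the gene of CD45, against 0.199% of the pool (82.5% and 0.596% unthinned). CD45-positive cells that passed the sort gate are a candidate explanation. Whether the tissues also differed in lymphocytes was not tested.

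For the largest ratios between the libraries, UMIs assigned to the other of near-identical gene copies may explain C1rb, C1s2 and Tpm3-rs7. The CPM of C1rb and C1s2 summed with C1ra and C1s1 differed by an absolute log2 ratio of at most 0.158. The sum of Tpm3-rs7 with Tpm3 differed by 0.09. For Trim12a moved UMIs may explain only a part. Its partner Trim12c had 17.7 CPM in ff and 31.8 CPM in GF. Their sum was 44.55 and 31.9 CPM, an absolute log2 ratio of 0.482, which is under the bound of 1.5-fold. Of Gbp2b and Isoc2b, 0 of 2 had a partner that differed the opposite way, which argues against this for them. For Pnp2 it stays open, because its CPM in ff was 1.52% of that of its partner Pnp, too little for moved UMIs to show there. Another mixture of clusters is argued against by weighting GF clusters by the ff shares, which left the median log2 ratio of the 24 genes, signed by direction, at 3.35, from 3.28. Ranked without the rule on classes, the same 24 genes came first. In the smooth muscle-like cluster 22 of the 24 differed at least 2-fold the same way, but free fibroblast RNA in these droplets could give the same ratios and is not excluded. Strain and germ-free status cannot be told apart, because the strain differs between the libraries and the status is given only by the name GF.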

How the results depend on the processing

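Comparisons with the named classes alone, with the pool as denominator and without differing genes were chosen after seeing the data. No paired analysis was possible because each group has 1 library and the cells carry no pairing. The cause was not tested for any value below that differs from the reported one.

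Under the alternatives, the Foxl1-high-like share ranged from 17.3% to 18.4% in ff and from 6.83% to 8.23% in GF; with doublets kept it was 18.4% and 7.72%, and of the pool 8.23% in GF. The Cxcl12 log2 ratio of Foxl1-high-like over other cells in ff was 0.78 with the laxer filter, 0.74 with doublets kept, 0.77 at Leiden resolution 2, 0.68 with median-of-ratios scaling, 0.77 with totals without mitochondrial and ribosomal protein genes and 1.58 against named classes alone. In GF it was 0.16 with the stricter filter, -0.12 with median-of-ratios scaling, 0.0307 with totals without mitochondrial and ribosomal protein genes, 0.0129 as the mean of per-cell CPM, -0.0326 thinned and 0.92 against named classes alone.

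For GF over ff, the stricter filter gave -0.0577 in the pool (also -0.0577 with the pseudocount), -0.52 in Foxl1-high-like and 0.11 in other cells. Median-of-ratios scaling gave 0.0494, -0.59 and 0.22, thinning 0.11, -0.54 and 0.30, and GF clusters weighted by ff shares 0.11, -0.63 and 0.32. The mean of per-cell CPM gave 0.10 in the pool and 0.28 in other cells, named classes alone -0.38 and 0.18, and doublets kept -0.42 in Foxl1-high-like cells. The negative ratio in Foxl1-high-like cells and the positive one in other cells held under each alternative run, and the pool's sign did not.

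The BMP ligand median for GF over ff was 0.0520 with weighted clusters. The BMP antagonist median for Foxl1-high-like over other cells was 0.16 in ff and 0.55 in GF with at least 500 UMIs per gene. Lists standing apart numbered 10 to 14 for GF against ff and 12 to 15 between classes. Retinoid, heat shock, cholesterol, hypoxia and growth factor lists stood apart in all 10 settings.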
